A study of Mus musculus with 6 samples.

How the data were processed

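Mouse bone marrow cells negative for CD45 and Ter119 and positive for CD73 were sorted by CD105 into CD73+CD105- (n = 3) and CD73+CD105+ (n = 3) samples, and total RNA was biotin-labelled and hybridised to 1-colour arrays, 1 array per sample, per the labels. The tissue had been dissociated before sorting, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

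The deposited values are log2 expression values per probe set made by the authors with RMA, a background correction, quantile normalization and summary of probes into probe sets, per the submitters' processing notes. The software version, the probe annotation and the genome build are not given in the sources used here. Scanner files were not used here, so there were no detection calls and no other background correction was run. Array medians were 6.35, 6.31 and 6.31 for CD73+CD105- replicates 1, 2 and 3, and 6.27, 6.35 and 6.31 for CD73+CD105+ replicates 1, 2 and 3, with values between 1.46 and 13.9. Over the genes tested, Pearson's r between arrays was 0.992 to 0.995 within a group and 0.984 to 0.991 between groups, across genes, which are not independent replicates. The 5 principal components of the 6 arrays held 49.2%, 19.1%, 18.1%, 12.6% and 1.07% of the variance. For each probe set the mean of the replicate 1 arrays lay close to the mean of the other 4 (SD 0.0627 log2), a relation that no label describes and that the 8 other cross-population pairs did not show (lowest SD 0.202). RMA compresses differences near background, so folds of dim genes may be understated.

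Of 35556 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 had none here. Of the 21789, 21698 were matched to a reference gene table by Entrez ID, and 0 symbols changed. Only probe sets with 1 symbol were used, and for the 999 genes with several such probe sets the one with the highest mean over all 6 arrays was taken, which gave 19938 genes. Among the genes past the threshold 19 had several probe sets, and in 3 of these another probe set differed in the opposite direction. As a level for genes that marrow is not thought to use, the 95th percentile of the means of 1194 olfactory and vomeronasal receptor genes was 6.01 (median 4.05). No filter on dim genes was applied. Of the genes past the threshold, 85 of those higher in CD73+CD105+ cells lay below this percentile in CD73+CD105- cells, 14 of those lower lay below it in CD73+CD105+ cells, and 3 were themselves receptor genes (Olfr1423, Olfr316 and Olfr44, named after their values were seen). No coordinates are given, since no build is named.

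Differences were tested on the log2 values with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, CD73+CD105+ minus CD73+CD105-, with no block, and p-values were adjusted by Benjamini-Hochberg over the 19938 genes with a threshold of 0.05. Standard errors are the moderated ones of that fit. At an unadjusted p under 0.05 there were 3522 genes. Before the data were examined, 30 gene lists with 459 gene symbols were fixed, of which 411 were measured and 24 stood in more than 1 list. The lists covered marrow stroma, endothelium, perivascular cells, other cell types the gates could hold, matrix, signalling and cell state. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists, and again with the correlation estimated per list. The estimated setting also refers its statistic to the few residual degrees of freedom of the arrays, and the preset one to the number of genes. Its p-values are therefore larger at the same statistic, also where the estimated correlation is small. The directional test fry was run beside them, which asks whether a list's genes move one way on balance and does not compare them with other genes. A rule fixed at the same time named the genes: the sort marker genes, of which 1 is not reported here, the 10 largest increases and the 10 largest decreases among genes past the threshold with separated groups and a symbol that is not a gene model, clone or non-coding class, and from each list up to 4 members past the threshold. Where fewer than 2 members passed, the 2 with the largest difference were named.

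The tests were tried on simulated data drawn from the mean and spread of these 19938 genes, 3 arrays against 3. Of 100 genes changed by 1 on the log2 scale 85% were recovered, and of 100 changed by 2, 98% were; 9 of 192 calls (4.69%) were false. A list of 20 genes shifted by 0.5 was called and 0 of 29 unshifted lists were. The simulated genes were drawn independently, while the estimated correlation was 0.64 in the chondrocyte list and 0.74 in the immediate early list. The simulation therefore does not show how often camera at 0.01 calls unshifted lists of correlated genes. With no true difference, 5.27% of genes had p under 0.05 in independent arrays. Arrays with replicate 1 balanced exactly for every gene gave 9.65% without a batch term and 5.32% with it, and 0 genes passed the adjusted threshold in each case. The balance in the data was close but not exact (SD 0.0627), so 9.65% does not measure the excess here.

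Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array, filters on dim genes, other rules for several probe sets, a second quantile normalization, median centring, eBayes with trend and robust, array weights, stricter thresholds and other list tests. A batch term that sets replicate 1 apart from replicates 2 and 3, and a fit of replicates 2 and 3 alone, were added after the data were seen.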

Results

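Transcripts were measured in mouse bone marrow cells that lacked CD45, found on leukocytes, and Ter119, found on red cell precursors, and that carried CD73, a surface enzyme that makes adenosine. Cell sorting divided them by CD105 (endoglin, a co-receptor for TGF-beta family ligands) into CD73+CD105- cells (n = 3) and CD73+CD105+ cells (n = 3), collected straight into lysis buffer. The labels call the 3 samples of each group biological replicates and do not say whether they came from separate animals, so p-values measure the spread between these samples. Each array gave RMA log2 values for 35556 probe sets, from which 19938 genes were tested, and the array medians lay between 6.27 and 6.35. The number of arrays limits the precision: the median standard error of a difference was 0.0928 on the log2 scale. The series concerns the engraftment of marrow stroma alongside stem cell transplants, and the design asks how 2 stromal fractions that differ in CD105 differ in transcripts. All differences are CD73+CD105+ minus CD73+CD105- on the log2 scale.

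CD73+CD105+ cells held far more transcript of pan-endothelial genes than CD73+CD105- cells, with the junction genes Pecam1 and Cdh5 at 12.4 and 10.1 times the CD73+CD105- level. Of 17 genes of Lepr-expressing reticular stroma 8 rose, and of 17 haematopoietic niche factors, secreted or on the cell surface, 6 did, among them Vcam1 (2.46-fold), Kitl (2.41-fold) and Cxcl12 (2.48-fold). With a batch term for replicate 1, added after the data were seen, 2 genes of each list passed, and Kitl and Cxcl12 did not (adjusted p = 0.052 and 0.10). With the replicate number as a block, fixed beforehand, Kitl and Cxcl12 passed (0.0415 and 0.0117), though no label says that the numbers pair samples. No list passed camera with both the batch term and an estimated correlation, a setting that tests on the few residual degrees of freedom of the arrays. There the adjusted p was 0.0895 for the pan-endothelial list and 0.0766 for both the reticular stroma and niche factor lists. Cartilage genes, with a median level of 11.87 in CD73+CD105- and 11.48 in CD73+CD105+ cells, were lower as a list with a median difference of -0.30 (camera adjusted p = 7.58e-06; adjusted p = 0.35 with an estimated correlation). In limma, 363 of the 19938 genes differed at a Benjamini-Hochberg adjusted p under 0.05, 270 higher and 93 lower in CD73+CD105+ cells. The batch term left 101 (95 higher and 6 lower), and leaving out 1 array gave 86 to 293. At least 2-fold differences were found for 98 of the higher and 3 of the lower genes, Slc27a6 (-1.13) and, named after their values were seen, BC031361 (-1.43) and 4930524J08Rik (-1.64). In all 363 genes the 3 arrays of one group lay above the 3 of the other. Selection by p favours such genes, so this separation is no further evidence for them. Over all genes 23.7% were separated in this way, against 10% by chance if the arrays were exchangeable. The balance of the replicate 1 arrays described above breaks that assumption. The 10% is therefore no fair baseline here, and no conclusion is drawn from the comparison.

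Among the sort markers, Eng, which encodes CD105, was 3.38-fold higher in CD73+CD105+ cells, at 8.06 ± 0.25 (SD, n = 3) against 6.30 ± 0.21 (SD, n = 3), with a difference of 1.76 (SE 0.15, adjusted p = 0.00322). In replicates 2 and 3 alone the Eng difference was 1.60 and its adjusted p 0.0915. Nt5e, which encodes CD73, stood at 10.63 ± 0.12 in CD73+CD105- and 10.37 ± 0.08 in CD73+CD105+ cells, a difference of -0.26 that did not pass (SE 0.09, adjusted p = 0.183). Ptprc, which encodes CD45, was at 4.71 ± 0.05 and 4.70 ± 0.06, below the 95th percentile of olfactory and vomeronasal receptor genes (6.01), with a difference of -0.01 (SE 0.07, adjusted p = 0.96), whose sign changed when the arrays were quantile normalized again or centred on their medians.

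Leaving out gene models and clones, the 10 genes with the largest increases rose between 9.23-fold and 26.5-fold. Cd36, a fatty acid transporter, rose by 4.73 (SE 0.24, adjusted p = 0.000318), from 4.52 ± 0.23 to 9.25 ± 0.48 (SD, n = 3 each). Emcn, a sialomucin of venous and sinusoidal endothelium, rose by 4.61 (SE 0.27), and Fabp4, a fatty acid binding protein of adipocytes and capillaries, by 4.12 (SE 0.11). The endothelial adhesion receptor gene Adgrl4 rose by 4.07, the ATP-degrading ectoenzyme gene Entpd1 by 3.76 and Pecam1 by 3.63, and the protease inhibitor gene Ctla2a rose 16.1-fold. Cd93, a lectin-like endothelial receptor, rose by 3.51, Cdh5, the cadherin of endothelial junctions, by 3.34, and the monooxygenase gene Fmo2 by 3.21. The adjusted p-values of these 10 genes were at most 0.0031. In 7 of the 10 the CD73+CD105- mean lay below the receptor gene percentile, so those folds may understate the difference.

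The 10 largest decreases, chosen in the same way, were smaller. Slc27a6, a fatty acid transport protein, fell by 1.13 (SE 0.18, adjusted p = 0.0331), which is 2.18-fold. Ube2cbp fell by 0.91, Mob2 by 0.88, the mitotic kinesin gene Kif4 by 0.81, Cyb5d1 by 0.78, Usp6nl, a GTPase-activating protein, by 0.77, the connexin gene Gjc3 by 0.75 and Pxylp1, a xylose phosphatase of proteoglycan synthesis, by 0.73. Erich6 (-0.88) and Lekr1 (-0.83) also passed, with both group means below the receptor gene percentile. The adjusted p-values of these 10 genes were at most 0.0347.

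**Figure D1:**
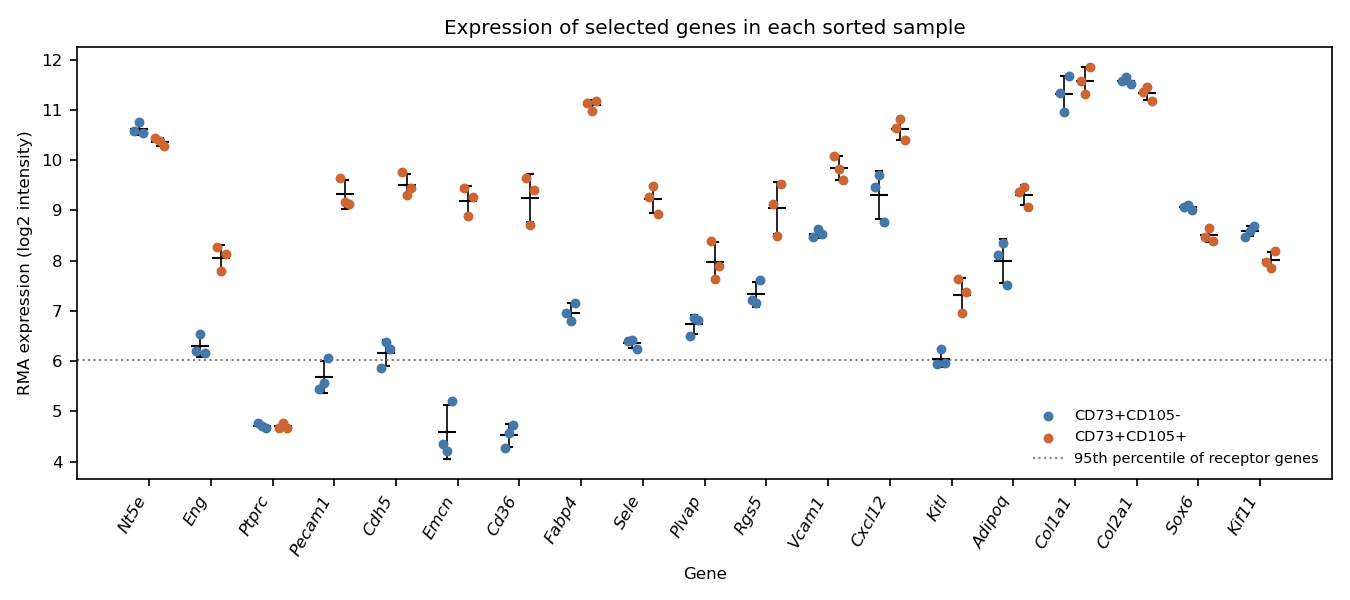
RMA log2 expression of 19 genes in each sorted sample, with points for the 3 samples of each population, a bar at the mean and whiskers of 1 SD; the dotted line is the receptor gene percentile at 6.01. For Pecam1, Cdh5, Emcn, Cd36 and Fabp4 the 3 CD73+CD105+ points lie above all CD73+CD105- points, and Ptprc lies under the dotted line in all 6 samples.

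Of 18 measured pan-endothelial genes, 13 rose, 0 fell and 5 did not pass, and 18 rose when adjusted over the list alone. The 5, named after their values were seen, were Cldn5 (0.31) and the transcription factor genes Sox18 (0.88), Fli1 (0.47), Erg (0.31) and Sox17 (0.25). Erg and Fli1 already stood at 8.88 and 8.09 in CD73+CD105- cells. The list median was 1.23 (camera adjusted p = 4.58e-30). With an estimated correlation the camera adjusted p was 0.0486, and with the batch term for replicate 1 as well 0.0895. Emcn, Pecam1, Cdh5 and Ptprb, a receptor phosphatase of vessels that rose by 2.94 (SE 0.11, adjusted p = 0.000123), changed most. Of 12 sinusoidal endothelial genes 1 rose, Plvap, the diaphragm protein of fenestrated vessels, at 2.37-fold (adjusted p = 0.0306), and 5 rose adjusted over the list alone. Lyve1, a hyaluronan receptor of sinusoids, differed by 0.44 and did not pass (adjusted p = 0.0628). The sinusoidal list had a median of 0.17 (camera adjusted p = 0.000518; adjusted p = 0.168 with an estimated correlation), and 6 of its members lay below the receptor gene percentile in both populations. Of 16 arteriolar endothelial genes 2 rose, the elastic fibre gene Fbln5 (1.82-fold) and Podxl (1.71-fold), a sialomucin of vessel linings, and 5 rose adjusted over the list alone (median 0.20, camera adjusted p = 0.000147; adjusted p = 0.0939 with an estimated correlation). Of 14 pericyte and smooth muscle genes 4 rose and 0 fell, against 7 and 1 adjusted over the list alone. They were Rgs5, a regulator of G protein signalling in pericytes (3.3-fold), Tagln, an actin-binding protein of smooth muscle (1.97-fold), Abcc9, a subunit of potassium channels (1.58-fold), and Mcam, the adhesion molecule CD146 (1.49-fold). Their list median was 0.32 (camera adjusted p = 0.000141; adjusted p = 0.119 with an estimated correlation).

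Among 17 Lepr-expressing reticular stroma genes, 8 rose, 0 fell and 9 did not pass, and 14 rose adjusted over the list alone. With the batch term for replicate 1, 2 rose over all genes. Adipoq, the adipokine adiponectin, rose by 1.32 (SE 0.22, adjusted p = 0.0337), Cxcl12, the chemokine that retains blood stem cells, by 1.31 (SE 0.23, adjusted p = 0.044), Vcam1, an adhesion molecule, by 1.30 (SE 0.12, adjusted p = 0.00544) and Kitl, stem cell factor, by 1.27 (SE 0.18, adjusted p = 0.0201). Lepr itself, named after its values were seen, rose by 0.93 (SE 0.10, adjusted p = 0.00869). The list median was 0.83 (camera adjusted p = 2.68e-14; adjusted p = 0.0476 with an estimated correlation). Of 17 haematopoietic niche factors 6 rose and 0 fell, or 9 and 0 adjusted over the list alone. With the batch term 2 rose over all genes. The niche list median was 0.53 (camera adjusted p = 5.53e-10, or 0.0486 with an estimated correlation). Besides Cxcl12, Vcam1 and Kitl, which both lists hold, Sele, the E-selectin of activated endothelium, rose by 2.87 (SE 0.14, adjusted p = 0.000272). Endothelial cells are also known to make Cxcl12, Kitl and Vcam1, and the pan-endothelial median in the same arrays was 1.23. With a batch term for replicate 1 added to the fit, the adjusted p was 0.0821 for Adipoq, 0.10 for Cxcl12 and 0.052 for Kitl. With the replicate number as a block it was 0.00839, 0.0117 and 0.0415 for these genes.

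In the adipocyte list 3 of 12 genes rose, Cd36, Fabp4 and Adipoq, 0 fell, and 4 rose adjusted over the list alone. Cd36 and Fabp4 are also known from capillary endothelium. The list median was 0.02 against a mean of 0.86 (camera adjusted p = 0.00328; adjusted p = 0.168 with an estimated correlation), and its median was -0.04 in replicate 1 and 0.11 in replicates 2 and 3. Of 17 fibroblast and tendon genes 1 rose, Cd34, a sialomucin of stromal progenitors and of endothelium (2.73-fold, adjusted p = 0.00264), and 11 rose adjusted over the list alone. Mfap5, a microfibril protein, differed by 0.87 and did not pass (adjusted p = 0.0562), and the list median was 0.35 (camera adjusted p = 9.54e-10; adjusted p = 0.144 with an estimated correlation). Of 13 osteoblast lineage genes 0 passed, over all genes or adjusted over the list alone, with Postn, a matrix protein of periosteum, at 0.47 and Ifitm5, a bone membrane protein, at 0.39 (4 with an unadjusted p under 0.05 in limma; median 0.12, camera adjusted p = 0.0637). Of 19 chondrocyte genes 1 fell, Sox6, a transcription factor of cartilage, by 0.56 (SE 0.09, adjusted p = 0.0304), and 4 fell adjusted over the list alone. Its partner Sox5 differed by -0.64 and did not pass over all genes (adjusted p = 0.0756). The difference was below 0 in 18 of the 19 chondrocyte genes, with a median of -0.30 (camera adjusted p = 7.58e-06; adjusted p = 0.35 with an estimated correlation).

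**Figure D2:**
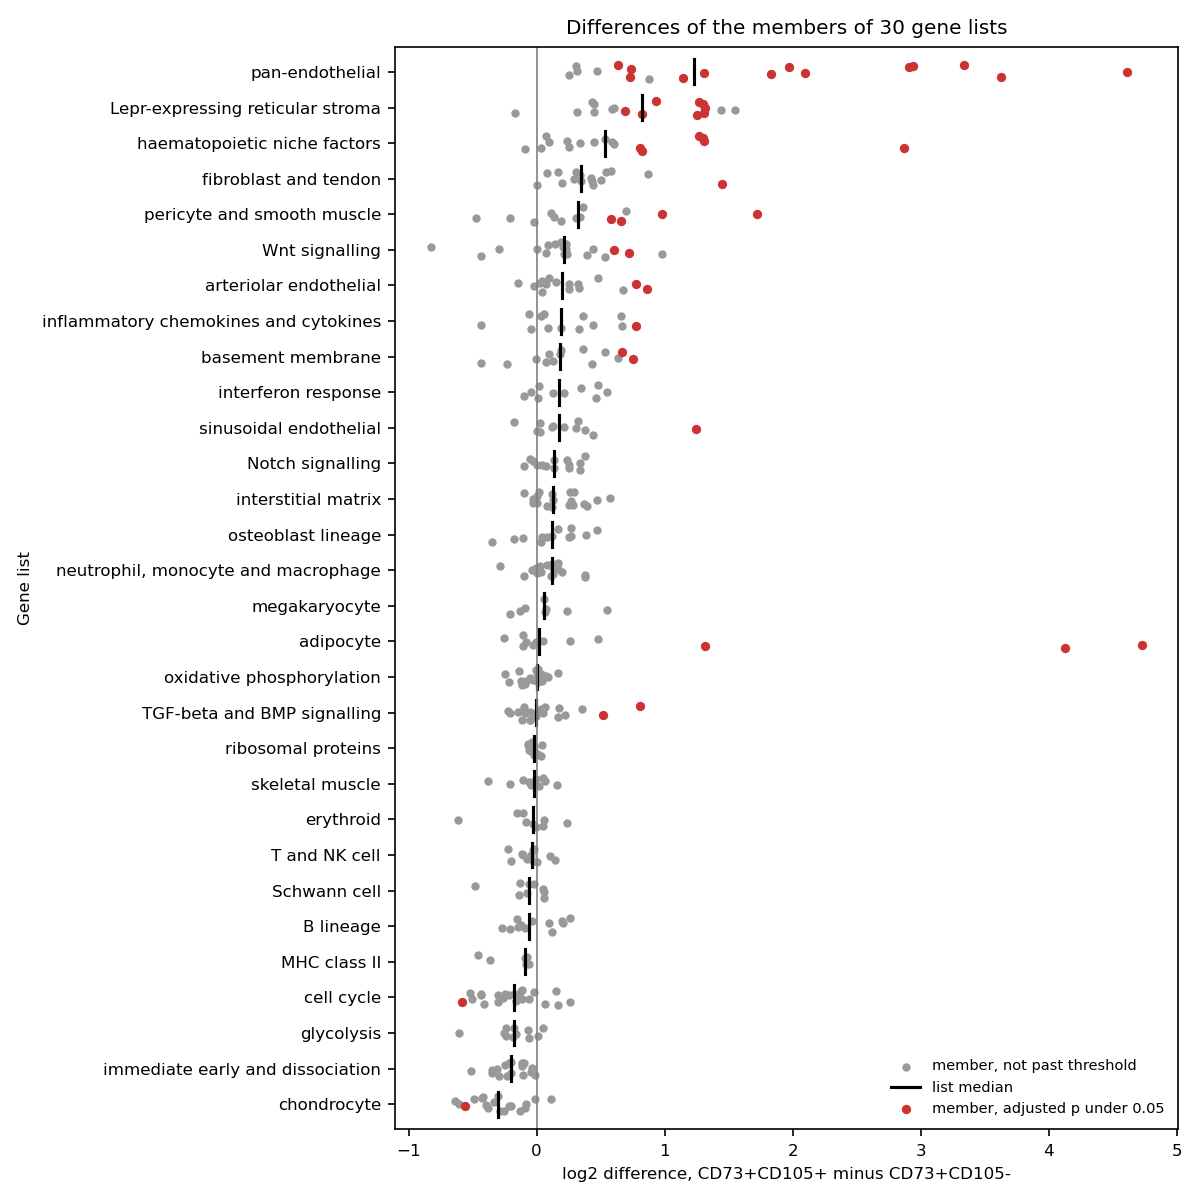
Log2 difference between CD73+CD105+ and CD73+CD105- cells for each measured member of the 30 gene lists, ordered by the list median (black bar), with members past the threshold in red. The pan-endothelial list has the highest median, at 1.23, and the chondrocyte list the lowest, at -0.30.

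Of 19 interstitial matrix genes 0 passed, 1 rose adjusted over the list alone, and Eln, elastin, and Postn were at 0.57 and 0.47 (5 with an unadjusted p under 0.05 in limma; list median 0.13, camera adjusted p = 0.00107; adjusted p = 0.187 with an estimated correlation). Of 14 basement membrane genes 2 rose, the laminin chains Lamc1 (1.68-fold) and Lama2 (1.59-fold), against 8 higher and 1 lower adjusted over the list alone (median 0.19, camera adjusted p = 0.000127; adjusted p = 0.119 with an estimated correlation). Among 21 genes of TGF-beta and BMP signalling 2 rose, the ligand Bmp4 (1.75-fold) and Acvrl1, an endothelial receptor that binds with endoglin (1.43-fold), and 3 rose adjusted over the list alone. The list median was -0.01, its mean 0.06, and the list did not pass (camera adjusted p = 0.203). Of 14 Notch genes 0 passed and 3 rose adjusted over the list alone, with the target Hey2 at 0.38 and the ligand Dll1 at 0.34 (4 with an unadjusted p under 0.05 in limma; median 0.13, camera adjusted p = 0.00319; adjusted p = 0.119 with an estimated correlation). Without the genes that stand in several lists the Notch camera adjusted p was 0.128, and over genes above the median level 0.219. The Notch call held over genes above the receptor gene percentile. Of 19 Wnt genes 2 rose, the receptor Fzd6 (1.65-fold) and the secreted antagonist Sfrp4 (1.52-fold), against 4 higher and 2 lower adjusted over the list alone (median 0.22, camera adjusted p = 0.000518; adjusted p = 0.199 with an estimated correlation).

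Among 10 interferon response genes 0 passed and 3 rose adjusted over the list alone, with the antiviral genes Ifit3 at 0.55 and Ifit1 at 0.48; 3 had an unadjusted p under 0.05 in limma. The list shifted up (median 0.17, camera adjusted p = 0.0168; adjusted p = 0.175 with an estimated correlation), and its adjusted p was 0.077 without CD73+CD105- replicate 3. Of 13 inflammatory chemokines and cytokines 1 rose, Ccl19, a chemokine that attracts lymphocytes (1.71-fold, adjusted p = 0.0316), and 2 rose adjusted over the list alone. Ccl2, which attracts monocytes, differed by 0.67 and did not pass (adjusted p = 0.0552). The list median was 0.19 (camera adjusted p = 0.00976; adjusted p = 0.187 with an estimated correlation; 0.174 by camera without CD73+CD105- replicate 3). Of 6 MHC class II genes 0 passed over all genes and 2 fell adjusted over the list alone, with H2-DMa at -0.46 and H2-Ab1 at -0.36 (2 with an unadjusted p under 0.05 in limma; median -0.09, camera adjusted p = 0.0559). By camera the class II list passed without CD73+CD105- replicate 3 (adjusted p = 0.0239), without CD73+CD105+ replicate 1 (0.0342) and without CD73+CD105+ replicate 2 (0.0351). The osteoblast list passed without CD73+CD105- replicate 3 (0.0278) and without CD73+CD105+ replicate 2 (0.0358). Both also passed with the replicate block (0.0436 and 0.0238) and on ranks (0.0486 and 0.039). Class II passed over genes above the median level (0.0468), and the osteoblast list with array weights (0.0359). With an estimated correlation in all 6 arrays the class II and osteoblast adjusted p was 0.36 and 0.273.

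Of 23 cell cycle genes 1 fell, Kif11, a spindle motor (1.5-fold, adjusted p = 0.0456), and 5 fell adjusted over the list alone, while Cdc20, an activator of mitotic exit, was at -0.52 and did not pass (adjusted p = 0.0873). The list median was -0.17 (camera adjusted p = 0.00107; adjusted p = 0.288 with an estimated correlation). None of the 17 immediate early and dissociation genes passed over all genes or over the list alone (0 in limma), with Ier2 at -0.51 and Btg2 at -0.35. All 17 differences of that list lay below 0 (median -0.20, camera adjusted p = 0.0014; adjusted p = 0.503 with an estimated correlation). Of 11 glycolysis genes 0 passed by either adjustment, with Hk2 at -0.61 and Pkm at -0.25 (median -0.18, camera adjusted p = 0.0184; adjusted p = 0.32 with an estimated correlation; 0.0644 without CD73+CD105- replicate 3 and 0.0758 without CD73+CD105+ replicate 3). The 21 oxidative phosphorylation genes held 0 past the threshold, with Ndufs1 at -0.25 and Cox5a at -0.22 (median 0.00224, mean -0.03, camera adjusted p = 0.856). The 15 ribosomal protein genes also held 0, with Rpl8 at -0.07 and Rps3 at -0.06 (median -0.02, camera adjusted p = 0.669), and neither of these lists held any adjusted over the list alone. At an unadjusted p under 0.05 limma counted 4 immediate early, 4 glycolysis, 1 oxidative phosphorylation and 0 ribosomal protein genes.

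Lists for other cell types of marrow and adjoining tissue held 0 genes past the threshold in limma. At an unadjusted p under 0.05 limma counted 1 Schwann cell, 1 skeletal muscle, 3 B lineage, 1 T and NK cell, 1 erythroid, 1 megakaryocyte and 2 neutrophil, monocyte and macrophage genes. There were 9 Schwann cell genes with S100b at -0.48 and Ncam1 at -0.14 (median -0.06, camera adjusted p = 0.479; 1 lower adjusted over the list alone), and 10 skeletal muscle genes with the troponins Tnni2 at -0.38 and Tnnt3 at -0.21 (median -0.02, camera adjusted p = 0.856). The 12 B lineage genes, with Vpreb3 at -0.27 and Vpreb1 at 0.26, had a median of -0.06 (camera adjusted p = 0.701). The 12 T and NK cell genes, with Cd247 at -0.23 and Il2rb at -0.20, had a median of -0.04 (camera adjusted p = 0.575). The 9 erythroid genes, with the transferrin receptor Tfrc at -0.62 and Car1 at 0.24, had a median of -0.03 (camera adjusted p = 0.669), and the 8 megakaryocyte genes, with the platelet chemokines Ppbp at 0.55 and Pf4 at 0.23, one of 0.06 (camera adjusted p = 0.575). In the muscle, B, T and NK, erythroid and megakaryocyte lists 0 genes passed adjusted over the list alone. The 18 neutrophil, monocyte and macrophage genes, with the granule gene Ngp at 0.38 and lysozyme Lyz2 at 0.38, held 0 past the threshold and 1 higher adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.0319; adjusted p = 0.503 with an estimated correlation), at -0.07 in replicate 1 and 0.17 in replicates 2 and 3, and the list did not pass without CD73+CD105- replicate 3 (adjusted p = 0.384) or CD73+CD105+ replicate 2 (0.163). Of the 59 members of the 5 blood cell lists, 36 lay below the receptor gene percentile in both populations.

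By camera 15 lists shifted up, 4 shifted down and 11 did not pass, and 3 calls held with an estimated correlation: pan-endothelial, Lepr-expressing reticular stroma and haematopoietic niche factors. The replicate 1 arrays balanced the other 4: the mean of the 2 replicate 1 arrays minus the mean of the other 4 had an SD of 0.0627 over probe sets, against 0.202 to 0.244 for the 8 other cross-population pairs. A batch term for replicate 1, added after this was seen, left each difference as it was and reduced the calls to 101, of which 95 were higher and 6 lower. Those kept among the 44 named genes past the threshold were 17: Eng, the 10 genes with the largest increases, Vcam1, Sele, Cd34, Ptprb, Fbln5 and Tagln. The same 17 passed in all 6 fits that left out 1 array, and the other 27 did not. None of the 10 named genes with the largest decreases passed with the batch term (adjusted p 0.0505 to 0.0924). With the replicate number as a block, Slc27a6, Lekr1, Kif4, Cyb5d1, Usp6nl and Gjc3 passed (adjusted p 0.0268 to 0.0495), while Ube2cbp, Erich6, Mob2 and Pxylp1 did not. No list passed with both the batch term and an estimated correlation, where pan-endothelial was at 0.0895, reticular stroma at 0.0766 and niche factors at 0.0766. In replicates 2 and 3 alone 29 genes passed (28 higher and 1 lower, 4930524J08Rik). With 1 array left out the calls numbered 87 without CD73+CD105- replicate 1, 150 without replicate 2 and 292 without replicate 3 of that group, and 86, 293 and 169 without CD73+CD105+ replicates 1, 2 and 3. Within replicate 1 alone the median was 1.49 for pan-endothelial, 0.91 for reticular stroma, 0.54 for niche factor and -0.22 for chondrocyte genes, and in replicates 2 and 3 it was 1.09, 0.89, 0.41 and -0.33. Over the 19 lists that passed by camera, the median lay on the called side in both subsets in 17, the exceptions being the adipocyte and the myeloid list.

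**Figure D3:**
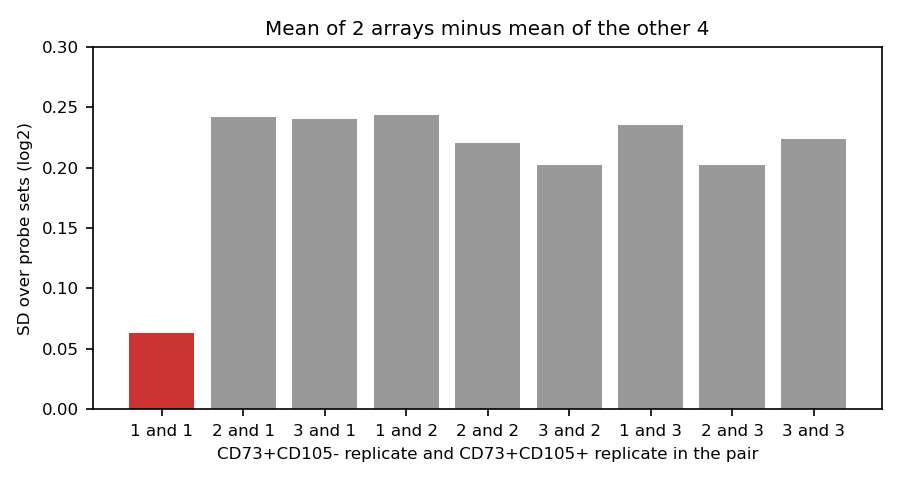
SD over 35556 probe sets of the mean of 1 CD73+CD105- and 1 CD73+CD105+ array minus the mean of the other 4 arrays, for the 9 possible pairs named by their replicate numbers. The pair of both replicate 1 arrays, in red, is at 0.0627, and the other 8 pairs are between 0.202 and 0.244.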

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

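The batch term for replicate 1 and the fit of replicates 2 and 3 alone were chosen after seeing the data, and the other settings before. Against 363 genes (270 higher, 93 lower), the batch term gave 101 (95 higher, 6 lower; 94.1% of calls higher against 74.4%), all among the 363, and the same calls for all 30 lists. It leaves every fold as it was and has fewer residual degrees of freedom. Standard errors changed as well, from 0.153 to 0.164 for Eng and from 0.0861 to 0.103 for Nt5e. Which of these ended the calls was not tested. Replicates 2 and 3 alone gave 29 (28 higher, 1 lower), with Eng at 1.60 (adjusted p = 0.0915; 0.0011 to 0.022 over the other settings), fewer samples being the setting's own construction. Array weights, which gave 2.44 to CD73+CD105+ replicate 1 and 1.61 to CD73+CD105- replicate 1, raised the count to 1331 (807 higher, 524 lower; 60.6% higher), and the cause was not tested. A requirement of 2-fold left 101 (98 higher, 3 lower) and an adjusted p under 0.01 left 77 (73 higher, 4 lower). Testing each probe set on its own called 179 higher and 126 lower (305 in all), and the cause was not tested. Leaving out 1 array gave 86 to 293 genes, 80 to 240 higher and 6 to 53 lower, Eng between 1.65 and 1.89, Nt5e between -0.31 and -0.19, Ptprc between -0.043 and 0.015, 13 to 15 lists up and 3 to 5 down, with fewer samples in each. An estimated correlation left 3 lists up and 0 down, and fry 11 up and 0 down. For the arteriolar and Notch lists the estimate (0.00305 and -0.0383) lay below the preset 0.01. Their unadjusted camera p still rose, from 3.92e-05 to 0.0125 and from 0.00149 to 0.0279. A correlation above the preset value therefore does not account for those rises. With an estimated correlation camera also takes p from the few residual degrees of freedom of the arrays. With a preset one it takes the far larger number set by the genes. That difference raises p at the same statistic, so list calls lost in this setting do not by themselves show correlation between genes. How much each part contributed was not tested. Dim-gene filters, means over probe sets, another quantile normalization, centring and a trended, robust eBayes kept the total between 319 and 398 and Eng past the threshold.

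Nothing in the labels says that replicate numbers pair samples, so no pairing was used. Across genes, same-numbered samples' deviations from the group means correlated at -0.88, 0.0066 and 0.10 for replicates 1, 2 and 3. The balance of the replicate 1 arrays fixes the first and bears on the others. CD73+CD105- replicate 3 with CD73+CD105+ replicate 2 was at -0.37, and CD73+CD105- replicate 2 with CD73+CD105+ replicate 3 at -0.32. Both lay below the same-numbered values of replicates 2 and 3, so a batch shared by number stays open. Not every sample correlated best with its own number. The balance itself raises the correlation of the replicate 1 arrays with other numbers, so best matches do not test pairing. A replicate block, which also sets replicate 1 apart, gave 215 genes (190 higher, 25 lower), against 101 with the batch term. Of the 215, 168 were among the 363. By camera it gave 16 lists up and 5 down, adding osteoblast lineage (adjusted p = 0.0238) and MHC class II (0.0436). Another background correction and a block for slide or scan date were not run, since neither scanner values nor dates were used here, and Ptprc has no value under the dim-gene filters. Signal near background limits the folds of the 85 higher genes whose CD73+CD105- mean lay below the receptor gene percentile.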

Other observations

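The tests here were chosen after the results were seen, except the count of other splits of the arrays and the camera tests of the interferon response and the neutrophil, monocyte and macrophage lists. Cartilage genes had some of the highest array signals in both populations, which also depend on the probes and do not rank transcripts by abundance. By mean signal, Cnmd (chondromodulin) stood at 13.01 in CD73+CD105- and 12.88 in CD73+CD105+ cells, Chad (chondroadherin) at 12.93 and 12.92, Prg4 (lubricin) at 12.76 and 12.87 and Comp, a cartilage matrix protein, at 12.83 and 12.74, beside ribosomal proteins and Sparc; all 4 were named after their values were seen. The median member of the chondrocyte list lay at the 98.7 percentile of gene signals, that of the immediate early list at 97.2 and that of the pan-endothelial list at 56.6.

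Interferon-inducible GTPases, which act against intracellular pathogens, were higher in CD73+CD105+ cells: 5 of 11 measured rose, 0 fell, and the median was 0.54. Iigp1 rose by 2.39 (SE 0.13, adjusted p = 0.000356), Gbp9 by 2.29 and Gbp4 by 1.61, and these 3 also passed with the batch term. The group was noticed in the data, so a hypothesis that gamma-interferon-inducible genes may shift together was tested on a separate list for antigen processing and MHC class I, of which Psmb8 had been seen before. Of its 11 measured members 4 rose and 0 fell (median 0.33). By camera with an estimated correlation its p was 0.00401, and 0.00908 with the batch term as well. Without Psmb8 these were 0.00652 and 0.0133. These p-values were not adjusted over lists, unlike those that decided the calls of the lists fixed beforehand. The pan-endothelial list had an unadjusted p of 0.00486 by camera with an estimated correlation, and an adjusted p of 0.0486. The unadjusted values therefore do not show that this list held better than the pan-endothelial list. With the batch term only Psmb8, which rose by 0.92, passed on its own, and Psmb9, an immunoproteasome subunit that rose by 1.07, did not (adjusted p = 0.0544). The interferon response list, made mostly of antiviral genes, gave an unadjusted p = 0.0641 by camera with an estimated correlation in limma (adjusted p = 0.175), which did not pass. Whether endothelial or reticular cells carry these transcripts stays open.

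The mean of the replicate 1 arrays equalled that of the other 4 more closely than for any other cross-population pair, with an SD 0.311 times the lowest of the 8. A candidate explanation is a per-gene adjustment of the deposited values that took both replicate 1 arrays as one set, which would give a low ratio. A pool of replicates 2 and 3 within each population as the replicate 1 sample is argued against as the sole source of the balance. Replicate 1 minus their mean had an SD of at least 4.07 times that of the balance. That ratio is high because the deviations of the replicate 1 arrays oppose each other, so it cannot exclude pools whose values were then adjusted. No biological explanation was tested. If an adjustment was made, the fit without a batch term counts 1 residual degree of freedom too many per gene, and its p-values would be too small. Simulated arrays with an exact balance, stricter than the one here, gave 9.65% of unchanged genes with p under 0.05.

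The pan-endothelial list had the highest median of the 30 lists (1.23), while the sinusoidal (0.17) and arteriolar (0.20) medians lay below that of reticular stroma (0.83). An added share of endothelial cells over an otherwise unchanged mix would lower all stromal lists alike. Against that, the reticular stroma list exceeded the chondrocyte list by 1.16 (SE 0.13 over samples). Without the niche factors, of which endothelial cells make some, it did so by 1.12 (SE 0.11). Both lists were compared after their shifts in opposite directions had been seen, and the SE does not allow for that choice. Blood cells as the source of the whole shift would raise their own transcripts about as much, but the 23 blood cell list members above the receptor gene percentile in either population, 22 of them by less than 1.5, had a median of -0.0325 (SD 0.21) and rose by at most 0.38, the other 36 lying below it in both; the neutrophil, monocyte and macrophage list shifted up (median 0.12, camera adjusted p = 0.0319, or 0.503 with an estimated correlation), so a small share stays open. A shift common to both replicate 1 arrays cancels in the difference between populations and so cannot make it; the medians in replicate 1 and in replicates 2 and 3 (at least 1.09) are for that reason no test, and an adjustment of another form was not tested. A CD105+ gate that holds endothelial cells and more reticular cells may give this pattern, as may reticular cells that express such genes; bulk arrays leave both open.

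The real split gave 363 genes and the highest of the other 9 splits of the 6 arrays gave 0, so 1 of 10 splits reached that count; 10 splits are too few for a share under 0.05.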
